A study of Mus musculus with 8 samples.

How the data were processed

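Whole-liver total RNA from 8 female mice, 4 with the ΔF508 change in Cftr and 4 wild-type littermates, was amplified to biotin-labelled cRNA and read on single-colour mouse bead arrays. The labels name GenomeStudio, without a version or settings, as the software of the authors. The values analysed were the deposited log2 values, 25697 probes on 8 arrays with 0 missing. The log2 unit was checked from the values. They reach 14.66, while the largest value of a 16-bit scanner is 16 on a log2 scale and 11.1 on a natural log scale. Whether the authors used plain log2 or a variance-stabilizing transform, and which background correction, is not stated, so the size of differences near background depends on steps that are not known here. The sorted values of the 8 arrays were equal to within 0.000351, so the deposited values had been quantile-normalized by the authors, and every array had a median of 6.46. Such scaling removes any difference in total signal between arrays, and a change shared by most transcripts would not be seen.

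The plan fixed before the data were examined was to start from the scanner signals with background correction by neqc and a filter on detection p. The scanner table has 8 signal columns among 32, named by position on 1 chip, and no label gives the position of a sample. Columns were not matched to samples by order or by value, and that table is not used here. The deposited values took its place, and the filter was set from them. The background level was the mode of the values, 6.18, plus 1.645 times the spread below the mode, 0.173, which gives 6.47. Probes above it on at least 4 arrays were tested, 12923 in all.

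Probes were named from the platform annotation, and a check through gene identifiers changed 0 symbols. Of all probes, 23978 had 1 gene symbol, 0 had several and 1719 had none, and 768 of the tested probes were unnamed. Each gene was represented by its tested probe of highest mean, which gave 9146 genes. Where the mean of a genotype lay under background, the difference of the other genotype from the background level is given as a lower bound. Tested probes of the same gene differed in sign for 73 of the 534 changed genes that had more than 1. Coordinates are not given because the array annotation names no genome build.

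Differential expression used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the single term) with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. The test was tried on simulated data of the same size and spread. It recovered 65% of probes changed by 0.5 on the log2 scale and 97% of those changed by 1, with 10 false calls. With no change simulated it made 0 calls. The list test recovered 10 of 10 changed lists and called 1 of 30 unchanged lists. The simulated probes varied independently of each other, so this trial does not give the rate of false calls for lists whose members move together. On the real arrays the correlation between members was estimated at 0.854 for the cholesterol synthesis list.

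The comparison, the test, the 33 gene lists (23 pathways and 10 cell types), the rule for named genes and most alternatives were chosen before the data were examined. Lists were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the 33 lists, and beside it by camera with the correlation estimated, by fry, and by an exact two-sided permutation of the mean list level over 70 assignments of the arrays, whose smallest p is 0.0286. Fry tests a list alone and does not compare it with other genes. List genes without a named probe were not analysed here, and those with probes under background entered only the alternative without a filter on dim probes. Named genes are the 12 largest rises and 12 largest falls past the threshold whose CF and WT arrays do not overlap, leaving out clone and predicted names, up to 4 members of each list past the threshold in order of adjusted p, and Cftr. The other list members named, including those that did not pass, were chosen after their values were seen.

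Replicate numbers 1 to 4 occur in both genotypes, but nothing states that equal numbers pair animals. For that reason the plan set no pairing in the main fit. Deviations from the genotype mean correlated across probes at -0.33, 0.06, -0.29 and 0.09 for the 4 equal-numbered pairs. These values cannot exclude pairing. The pairs numbered 1 and 3 hold CF 1 and WT 3, whose deviations correlated with each other at 0.586. Alternatives covered the filter on dim probes, a replicate block, array weights, another variance prior, other thresholds, the mean of all probes of a gene, cyclic loess on top of the deposited values, a floor at background, each array left out in turn, WT 3 and CF 1 left out, and the pancreas and intestine list level as a covariate. Arrays have no read depth, and their number limits the precision.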

Results

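Whole-liver RNA was profiled in young female C57BL/6 mice carrying the ΔF508 change in Cftr, the chloride channel gene mutated in cystic fibrosis (CF), and in their wild-type (WT) littermates. Mice were weaned at 21 days onto an enriched diet, drank a diluted polyethylene glycol and electrolyte laxative in place of water, and were killed at 23 days. There were 8 arrays, 4 from CF livers and 4 from WT livers, each from a different replicate. The arrays were single-colour mouse bead arrays that read each transcript as a fluorescence signal, and the values analysed were the deposited log2 expression values, which were already quantile-normalized. Expression is given below as log2 level, mean ± SD with n = 4 per genotype, and differences are CF minus WT with the standard error (SE) of the fit. The arrays have no read depth, so the number of arrays limits the precision. The median SE of a difference was 0.0889 on the log2 scale. The single comparison was CF against WT, and the series title names altered de novo lipogenesis as its question.

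The CF and WT livers differed in many transcripts, and the largest fall among the named genes was that of Scd1. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, was at 9.01 ± 0.87 in CF and 13.47 ± 0.10 in WT, 22.1-fold lower (difference -4.47 ± 0.35 SE, adjusted p = 9.14e-05). Among the major urinary protein genes, Mup6 was 21.9-fold lower (difference -4.45 ± 0.44 SE), Mup2 was 21.5-fold lower (-4.43 ± 0.70 SE), and Mup5 and Mup20 were lower by at least 3.14 and 2.16 on the log2 scale. These last are lower bounds against the background level of 6.47, as their CF means of 6.25 and 6.39 lay under it. The probes of this family share much sequence, so signal cannot be assigned to single members. Hamp, which encodes the iron-regulating hormone hepcidin, fell from 13.28 ± 0.28 in WT to 9.45 ± 2.15 in CF, and its paralog Hamp2 from 14.29 ± 0.15 to 10.44 ± 2.50. Both took the same order over the CF arrays, lowest in CF 1 and highest in CF 2. Whether their probes read separate transcripts was not tested, so these falls may not be independent. The other leading falls were Ces3b, a carboxylesterase (-3.07 ± 0.28 SE), Car3, carbonic anhydrase III (-2.84 ± 0.32 SE), A1bg (-2.51 ± 0.27 SE), and the cholesterol synthesis enzymes Fdps (-2.44 ± 0.54 SE) and Cyp51 (-2.37 ± 0.55 SE). The CF mean of A1bg, 6.50, lay close to the background level, with 2 CF arrays above it, so its fall may be larger than measured.

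The largest rises included Igf2, a fetal growth factor, at 11.67 ± 1.54 in CF and 8.94 ± 0.66 in WT (6.62-fold higher, adjusted p = 0.0207). Pde6c, a phosphodiesterase best known from cone photoreceptors, was 6.10-fold higher (difference 2.61 ± 0.16 SE), Sult2a6, a sulfotransferase, 5.88-fold higher (2.56 ± 0.40 SE), and Tceal5 4.45-fold higher (2.15 ± 0.32 SE). Rbm3, an RNA-binding protein induced by cold, rose 4.41-fold (2.14 ± 0.17 SE). Apoa4, an apolipoprotein of lipid-rich particles, rose 4.32-fold (2.11 ± 0.24 SE), and Eif4ebp3, a repressor of cap-dependent translation, rose 4.24-fold (2.08 ± 0.29 SE). Asns, asparagine synthetase, rose 3.82-fold (1.94 ± 0.26 SE), Igfbp1, an insulin-repressed IGF-binding protein, 3.64-fold (1.87 ± 0.47 SE), and Myh8, a developmental myosin, 3.54-fold (1.82 ± 0.41 SE). Ciart, a repressor of the circadian clock, rose 3.35-fold (1.75 ± 0.11 SE), and Acat1, the mitochondrial thiolase of ketone metabolism, had a difference of 1.81 ± 0.14 SE. In each of these 24 genes the 4 CF arrays lay on one side of the 4 WT arrays, as the rule for naming them required. Hamp2 lost its call in 5 of the 8 fits that left out a library, with adjusted p of 0.0562, 0.0528, 0.0627, 0.0556 and 0.0630 without WT 1, WT 2, WT 3, WT 4 and CF 3. Igf2 had adjusted p = 0.0568 without WT 3 and 0.0529 without WT 4, and Igfbp1 had 0.0594 without WT 1 and 0.0570 without WT 4. With WT 3 and CF 1 both left out, adjusted p was 0.105 for Igf2, 0.0768 for Hamp2 and 0.0575 for Myh8.

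**Figure D1:**
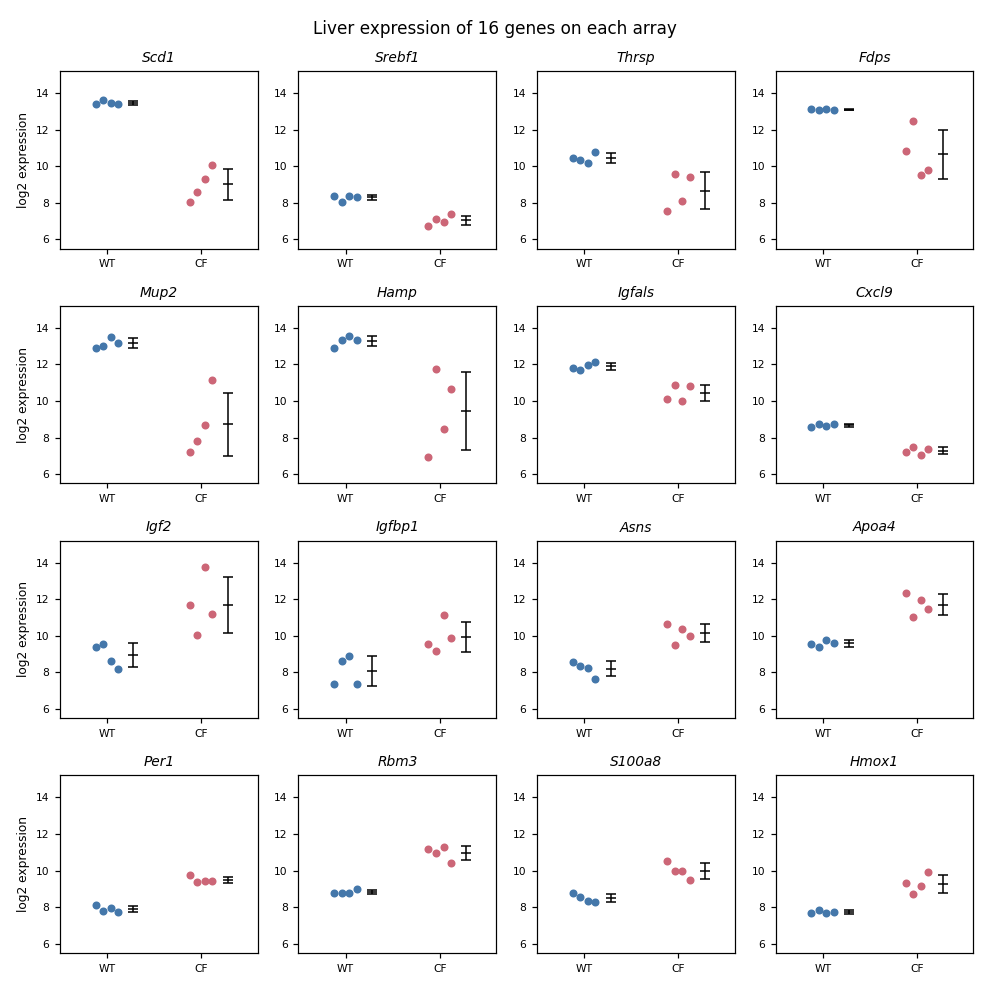
Log2 expression of 16 genes on each array, with WT in blue and CF in red; points are the 4 arrays of a genotype and the bar beside them is the mean ± SD. Scd1, Srebf1, Thrsp, Fdps, Mup2, Hamp, Igfals and Cxcl9 were lower in CF, and Igf2, Igfbp1, Asns, Apoa4, Per1, Rbm3, S100a8 and Hmox1 were higher; Scd1 moved from a mean of 13.47 in WT to 9.01 in CF.

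Of 12923 probes above background, 2474 changed between CF and WT (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05), 1337 higher in CF and 1137 lower, or 19.1% of those tested. Unadjusted p was under 0.05 for 4216 probes. With 1 probe per gene, 1812 of 9146 named genes changed, 1008 higher and 804 lower. The counts of changed members in the gene lists below can be read against these numbers. At least 2-fold changes numbered 61 higher and 91 lower, and at least 4-fold changes 7 higher and 18 lower. The 4 CF arrays lay entirely above or below the 4 WT arrays for 2230 genes, or 24.4%, where chance gives 2.86%. The first principal component, with 45.7% of the variance, separated the genotypes, and the next, with 21.2%, set WT 3 and CF 1 apart from the other 6 arrays. Without WT 3 the count of changed probes was 1612, and without both WT 3 and CF 1 it was 1060, with 531 higher and 529 lower.

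Genes of de novo lipogenesis, the synthesis of fatty acids from acetyl-CoA, were lower in CF, with 13 of the 17 members above background falling, 0 rising and 4 not passing (adjusted over the list alone, 14 fell). The list was lower than other genes by camera with a preset correlation (adjusted p = 9.86e-11) but not with the correlation estimated from these arrays (adjusted p = 0.0892 with an estimated correlation). Acly, the ATP citrate lyase that supplies cytosolic acetyl-CoA, was at 11.21 ± 0.13 in CF and 12.39 ± 0.07 in WT (difference -1.18 ± 0.08 SE, adjusted p = 5.11e-05). Acss2, which makes acetyl-CoA from acetate, fell by 1.99 on the log2 scale (SE 0.15), and Elovl6, a fatty acid elongase, fell by 1.56 (SE 0.13). The lipogenic transcription factors Srebf1 and Mlxipl had differences of -1.25 ± 0.13 SE and -0.93 ± 0.19 SE, and Thrsp, a lipogenic coactivator of the thyroid response, had -1.78 ± 0.41 SE. Acaca (acetyl-CoA carboxylase) fell by 0.61. Fasn (fatty acid synthase) was at 6.73 ± 0.05 in WT and under background in CF at 6.33 ± 0.21. This made it at least 0.265 lower on the log2 scale. The only tested Fasn probe was dim in WT too, little above background, where Acly was at 12.39. Whether this probe reads its transcript well was not tested. Neither the level of Fasn nor the size of its fall can therefore be judged from it. Pklr (-0.47), Elovl5 (-0.23), Fads2 (-0.29) and Insig1 (0.02) did not pass, and the other probes of Insig1 differed from it in sign. The list had a median difference of -0.63, and its mean level was 9.38 ± 0.16 in CF and 10.42 ± 0.03 in WT. The 4 CF arrays were all below the 4 WT arrays (two-sided exact permutation p = 0.0286, the smallest the design allows). Omission of single libraries gave 10 to 14 fallers. With WT 3 and CF 1 left out, 10 members passed, all lower.

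Cholesterol synthesis genes were lower as well, with 15 of 17 members falling, 0 rising and 2 not passing (adjusted over the list alone, 15 fell). The list median was -1.64, with a mean level of 8.86 ± 0.78 in CF and 10.32 ± 0.10 in WT (camera adjusted p = 8.09e-10; adjusted p = 0.327 with an estimated correlation). Dhcr7, the last reductase of the pathway, was at 7.88 ± 0.50 in CF and 9.53 ± 0.12 in WT, 3.13-fold lower (adjusted p = 0.00109). Hmgcs1, which makes HMG-CoA, was 3.47-fold lower (difference -1.80 ± 0.40 SE), and Nsdhl, a sterol dehydrogenase, 3.12-fold lower (-1.64 ± 0.26 SE). Pmvk, phosphomevalonate kinase, had a difference of -1.22 ± 0.18 SE. Srebf2, the sterol-responsive transcription factor, had a difference of -0.39 and did not pass. Omission of single libraries gave 11 to 16 fallers. With WT 3 and CF 1 left out, 6 of the 17 members passed, all lower. In that fit the differences of Fdps and Cyp51 were -2.49 and -2.45 with adjusted p of 0.0675 and 0.0689.

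Other lipid lists moved less uniformly and none of these 5 was called by camera. In triglyceride synthesis and storage, 4 of 21 members rose and 1 fell (adjusted over the list alone, 8 and 1). Pnpla2, the adipose triglyceride lipase, rose 1.94-fold (difference 0.95 ± 0.11 SE), and Plin5, a lipid droplet protein of oxidative tissue, rose 1.71-fold (0.77 ± 0.12 SE). Leaving out single libraries gave 3 to 6 risers and 0 to 2 fallers, with 0 fallers in each of these fits but the one without CF 1, and without WT 3 and CF 1 together 2 rose and 1 fell. In fatty acid oxidation and ketone synthesis, 9 of 21 rose and 2 fell (adjusted over the list alone, 10 and 2). Its risers included Acat1 and Fgf21, a fasting hormone (1.51 ± 0.30 SE), while Acaa1b, a peroxisomal thiolase, had -1.17 ± 0.24 SE (adjusted p = 0.0544 without WT 3 and CF 1). As single libraries were left out 1 or 2 fell, and the count of risers was 5 without WT 3, 5 without WT 4 and 4 without CF 1, and 2 with WT 3 and CF 1 both left out. Among other PPAR-alpha targets, 4 of 11 rose and 1 fell, the same numbers adjusted over the list alone. Cyp4a14, a fatty acid omega-hydroxylase, rose by 0.56 ± 0.11 SE from 13.06 ± 0.18 in WT. Leaving out single libraries gave 1 to 3 risers and 0 or 1 fallers in that list, and leaving out WT 3 and CF 1 gave 1 riser and 1 faller. In lipoproteins and lipid uptake, 3 of 17 rose and 0 fell (adjusted over the list alone, 3 and 0), namely Apoa4, Apoa5, an activator of triglyceride clearance (0.97 ± 0.11 SE), and Pltp, phospholipid transfer protein (0.46 ± 0.10 SE). Pltp had adjusted p = 0.0788 without WT 3 and CF 1, where 2 members rose. In bile acid synthesis and transport, 3 of 19 rose and 3 fell (adjusted over the list alone, 6 and 6). Abcb11, the bile salt export pump, was 3.40-fold lower (-1.77 ± 0.14 SE), and Cyp7b1, of the alternative synthesis pathway, 2.03-fold lower (-1.02 ± 0.10 SE). Nr1h4, the bile acid receptor FXR, rose 1.56-fold (0.64 ± 0.11 SE), and the median (0.05) and mean (-0.06) of that list differ in sign. Omission of single libraries gave 2 to 4 risers and 3 or 4 fallers, and with WT 3 and CF 1 left out, 1 member rose and 4 fell.

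Among genes of gluconeogenesis and the fasting response, 6 of 17 members rose in CF, 0 fell and 11 did not pass (adjusted over the list alone, 8 rose). The list median was 0.47 (camera adjusted p = 0.000266; adjusted p = 0.225 with an estimated correlation). Cebpb, a transcription factor of the fasted liver, was at 12.19 ± 0.07 in CF and 11.52 ± 0.17 in WT (adjusted p = 0.00129). The transaminase genes Got1 and Gpt2 rose by 1.17 (SE 0.16) and 0.59 (SE 0.08) on the log2 scale, and Igfbp1 belongs to this list too. The rate-limiting enzyme genes Pck1 (0.50) and G6pc (0.69) did not pass. The number of risers was 3 without WT 1, 3 without WT 4, and 5 without WT 3 and CF 1 together.

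Among targets of ATF4, the transcription factor of the amino acid response, 6 of 15 rose and 1 fell (adjusted over the list alone, 7 and 1; camera adjusted p = 0.0515). Asns and Fgf21 belong to this list, and Ddit4, an mTOR inhibitor, rose 2.14-fold (1.10 ± 0.19 SE). Risers numbered 6 or 7 as single libraries were left out, and fallers 0 without WT 1, WT 2, WT 3, CF 1, CF 2 or CF 3, while with WT 3 and CF 1 left out 3 rose and 0 fell. Of 15 ER chaperone and unfolded protein response genes, 1 rose and 3 fell (adjusted over the list alone, 1 and 5). Pdia6, a disulfide isomerase, fell by 0.75 (SE 0.08), and Sel1l, of ER-associated degradation, rose by 0.53 (SE 0.10) on the brighter of 2 probes that differed in sign. The fallers of that list numbered 1 to 5 as single libraries were left out. Without WT 3 and CF 1, 0 rose and 1 fell, with Sel1l at adjusted p = 0.0613. In glycolysis 1 of 7 members rose and 0 fell (adjusted over the list alone, 1 and 0), and in the immediate early genes 2 of 10 rose and 0 fell (adjusted over the list alone, 2 and 0). Tpi1, triosephosphate isomerase, differed by 0.34 ± 0.08 SE and Gadd45b, a stress-induced growth regulator, by 0.86 ± 0.14 SE. The 3 tested probes of Tpi1 did not all agree in sign, and its value is that of the brightest. As single libraries were left out, 1 or 2 immediate early genes rose, and 1 glycolysis gene fell without WT 1 and without CF 2. Without WT 3 and CF 1, 1 immediate early gene rose, and no glycolysis gene passed, with Tpi1 at adjusted p = 0.0725.

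Growth hormone and IGF axis genes went both ways, with 2 of 13 higher and 4 lower (adjusted over the list alone, 3 and 5). Igfals, which encodes the subunit that stabilises circulating IGF complexes, was at 10.44 ± 0.45 in CF and 11.91 ± 0.19 in WT, 2.76-fold lower (adjusted p = 0.00157). Ghr, the growth hormone receptor, fell by 0.67 (SE 0.09) and Serpina12 fell by 1.03 (SE 0.10). Leaving out single libraries gave 0 to 2 risers and 3 or 4 fallers, and leaving out WT 3 and CF 1 gave 1 and 4. Of 12 sex-biased liver genes, 3 rose and 6 fell (adjusted over the list alone, 3 and 7). Hsd3b5, a male-biased steroid enzyme, was at 8.06 ± 0.50 in WT and under background in CF, at least 1.59 lower on the log2 scale, and Cux2, a female-biased transcription factor, rose by 1.74 (SE 0.26). A1bg, also of this list, fell by 2.51 (SE 0.27) to a CF mean of 6.50, close to the background level. The members were not split by the direction of their sex bias, so these examples give no direction for the list. All 8 animals were labelled female, and leaving out single libraries gave 1 to 3 risers and 4 to 6 fallers in this list, with 1 and 4 without WT 3 and CF 1 together. Among fetal and maturing liver genes, 2 of 13 rose and 1 fell (adjusted over the list alone, 2 and 1). Besides Igf2, the oncofetal proteoglycan gene Gpc3 rose 2.57-fold (1.36 ± 0.31 SE), while Cyp1a2, an adult cytochrome P450, fell 2.50-fold (-1.32 ± 0.31 SE). Risers in that list numbered 1 without WT 3, 1 without WT 4 and 0 with WT 3 and CF 1 both left out, where Gpc3 had adjusted p = 0.0691.

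Among xenobiotic metabolism genes, 9 of 21 fell and 1 rose (adjusted over the list alone, 9 and 1). The list median was -0.29 (camera adjusted p = 0.00643; adjusted p = 0.352 with an estimated correlation). Cyp2b10, the classical target of the nuclear receptor CAR, was at 6.73 ± 0.34 in CF and 8.50 ± 0.15 in WT, 3.42-fold lower (adjusted p = 0.000184). Cyp2c55 was 2.92-fold lower, and Cyp3a13 was the riser, 1.88-fold higher. Its fallers numbered 5 without WT 2, 4 without WT 4, 5 without CF 3, and 5 without WT 3 and CF 1 together. The camera call was lost when only probes above background on all 8 arrays were tested. In fat-soluble vitamin and retinoid handling, 5 of 11 fell and 1 rose (adjusted over the list alone, 6 and 1). The median of this list was -0.18 (camera adjusted p = 0.00429; adjusted p = 0.213 with an estimated correlation). Ggcx, the vitamin K-dependent carboxylase, fell by 0.98 (SE 0.08), Rdh11, a retinol dehydrogenase, by 1.66 (SE 0.20) and Rdh16 by 0.46 (SE 0.09). As single libraries were left out 4 to 6 fell, with 0 risers without WT 1, WT 2, CF 1 or CF 3, and leaving out WT 3 and CF 1 together gave 3 fallers and 0 risers. Of 16 oxidative stress (NRF2) targets, 3 rose and 4 fell (adjusted over the list alone, 3 and 5), with 1 to 3 risers and 2 to 5 fallers as single libraries were left out, and 1 and 3 without WT 3 and CF 1 together. Hmox1, heme oxygenase 1, rose 2.88-fold (1.53 ± 0.21 SE), while Me1, which is also a lipogenic NADPH source, fell by 0.55 (SE 0.10).

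Among circadian clock genes, 7 of 14 rose in CF, 1 fell and 6 did not pass (adjusted over the list alone, 7 and 1). The list median was 0.45 (camera adjusted p = 0.0246; adjusted p = 0.213 with an estimated correlation). Per1, a clock repressor, was at 9.49 ± 0.17 in CF and 7.88 ± 0.16 in WT, 3.04-fold higher (adjusted p = 5.11e-05). Usp2, a clock-controlled deubiquitinase, rose 2.91-fold, Per2 rose 1.86-fold and the repressor Cry2 rose 1.55-fold. Nr1d1, the nuclear receptor REV-ERB alpha, fell by 0.42 (SE 0.10), and the activator Arntl differed by -0.04 and did not pass. Without WT 2, WT 3 or CF 3 the count of fallers was 0, and with WT 3 and CF 1 left out 6 rose and 0 fell. Of 12 heat shock genes, 3 fell and 0 rose (adjusted over the list alone, 3 and 0). The median was -0.22 (camera adjusted p = 0.0279; adjusted p = 0.213 with an estimated correlation). Hsph1 and Stip1, a chaperone and a cochaperone, fell by 0.84 (SE 0.11) and 0.59 (SE 0.08). The heat shock call by camera was lost without CF 2, with the median at -0.21, and at a stricter background level, and 2 fell with WT 3 and CF 1 left out. When only probes above background on all 8 arrays were tested, the camera calls of both the clock and the heat shock list were lost.

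Interferon-stimulated genes were lower in CF, with 14 of 24 falling, 0 rising and 10 not passing (adjusted over the list alone, 18 fell). The list median was -0.40 (camera adjusted p = 1.54e-09; adjusted p = 0.213 with an estimated correlation). Cxcl9, an interferon-gamma-induced chemokine, was at 7.29 ± 0.18 in CF and 8.67 ± 0.07 in WT, 2.61-fold lower (adjusted p = 5.53e-05). Gbp3, a guanylate-binding GTPase, fell by 0.82 (SE 0.08), Isg15, a ubiquitin-like modifier, by 0.85 (SE 0.11) and Ifit3 by 0.81 (SE 0.13). The number was 11 to 14 as single libraries were left out and 12 without WT 3 and CF 1 together. Among cell cycle genes, 9 of 19 fell and 0 rose (adjusted over the list alone, 12 fell). The median was -0.42 (camera adjusted p = 5.11e-07; adjusted p = 0.327 with an estimated correlation). Ccnd1, cyclin D1, was 2.95-fold lower (difference -1.56 ± 0.14 SE), Mcm5, of the replicative helicase, differed by -0.82 ± 0.15 SE, and Tyms, thymidylate synthase, by -0.59 ± 0.08 SE. The 4 tested probes of Tyms did not all agree in sign, and its value is that of the brightest. The cell cycle genes that fell numbered 6 to 10 as single libraries were left out and 5 with WT 3 and CF 1 left out.

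Neutrophil and myeloid precursor markers were higher in CF, with 7 of 13 rising and 0 falling (adjusted over the list alone, 10 and 1). The median was 0.67 (camera adjusted p = 0.000270; adjusted p = 0.327 with an estimated correlation). S100a8 and S100a9, the calprotectin subunits abundant in neutrophils, rose 2.80-fold and 2.60-fold, with S100a8 at 9.98 ± 0.42 in CF and 8.49 ± 0.23 in WT. Ltf, lactoferrin, rose by 0.92 (SE 0.16) from a WT mean of 6.65. Retnlg, a resistin-like gene, rose by at least 0.62 on the log2 scale, a bound against background because its WT mean of 6.37 lay under it. Omission of single libraries gave 7 or 8 risers, and 1 faller without WT 2 and without CF 4. With WT 3 and CF 1 left out, 7 rose, and of the 8 members left when only probes above background on all 8 arrays were tested, 3 rose and 0 fell. Of 14 Kupffer cell and macrophage markers, 1 rose and 0 fell (adjusted over the list alone, 0 and 0). That gene, Marco, a scavenger receptor, differed by 1.08 ± 0.30 SE with adjusted p = 0.0347, which was 0.0921 without WT 3, 0.0818 without WT 4, 0.0673 without CF 1, 0.0593 without CF 3 and 0.0776 without CF 4. Without WT 3 and CF 1 together, 0 macrophage markers rose and 1 fell. Of 11 T and B lymphocyte markers, 1 rose and 3 fell (adjusted over the list alone, 1 and 3). The MHC class II gene H2-Ab1 fell by 0.71 (SE 0.11) and the chemokine Ccl5 rose by 0.57 (SE 0.12). Leaving out single libraries gave 1 to 3 fallers, leaving out WT 3 and CF 1 gave 1 riser and 2 fallers, and the median (0.02) and mean (-0.12) of that list differ in sign. Of 23 acute phase genes, 5 rose and 2 fell (adjusted over the list alone, 6 and 2). Serpina3n, a protease inhibitor, rose 1.98-fold and Apcs, serum amyloid P, 2.22-fold, while Hamp was among the fallers. Risers numbered 4 to 6 and fallers 1 to 3 as single libraries were left out. Without WT 3 and CF 1, 3 rose and 1 fell.

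The counts for the other cell types, like those of the lists above, can be read against the 1812 of 9146 named genes that changed, 1008 higher and 804 lower. Of 15 endothelial markers, 3 rose and 0 fell (adjusted over the list alone, 3 and 0). Their median was 0.17 (camera adjusted p = 0.0279; adjusted p = 0.327 with an estimated correlation). Lyve1, a hyaluronan receptor of sinusoidal and lymphatic endothelium, rose 2.56-fold (1.35 ± 0.12 SE), and Vwf, von Willebrand factor, 1.40-fold (0.48 ± 0.07 SE). The endothelial call by camera was lost without WT 3, with a median of 0.16, without CF 3, with a median of 0.15, and when only probes above background on all 8 arrays were tested. Endothelial risers numbered 2 with WT 3 and CF 1 left out. Of 19 stellate cell and fibrosis genes, 2 rose and 2 fell (adjusted over the list alone, 2 and 2), with Ecm1, an extracellular matrix protein, at 0.44 ± 0.06 SE and Lum, lumican, at -0.56 ± 0.09 SE. Leaving out single libraries gave 1 or 2 in each direction, and leaving out WT 3 and CF 1 gave 1 in each. Of 9 cholangiocyte markers, 0 rose and 2 fell (adjusted over the list alone, 0 and 2), with Krt23, a keratin, at -0.99 ± 0.23 SE, while the biliary keratins Krt19 (0.01) and Krt7 (-0.01) did not pass. Fallers in that list numbered 1 or 2 as single libraries were left out, and 0 without WT 3 and CF 1 together, where Krt23 had adjusted p = 0.0884. Of 6 adipocyte genes, 0 rose and 2 fell (adjusted over the list alone, 0 and 2), Car3 and Adipoq, the gene of adiponectin (-0.40 ± 0.11 SE), and 1 or 2 fell as single libraries were left out, with 1 riser without CF 2. Adipoq lost its call without WT 2, WT 3, WT 4, CF 1 or CF 2 (adjusted p from 0.0652 to 0.0820), and 1 adipocyte gene fell without WT 3 and CF 1 together. Of 7 erythroid genes, 1 rose and 0 fell (adjusted over the list alone, 1 and 1), namely Klf1, an erythroid transcription factor, at 0.57 ± 0.07 SE. There was also 1 erythroid faller without WT 1, and 1 rose and 0 fell without WT 3 and CF 1. None of 17 hepatocyte markers passed in limma, so 0 rose and 0 fell (adjusted over the list alone, 0 and 0). At unadjusted p under 0.05 there were 3, Asgr1 (0.28), Asgr2 (-0.24) and Hnf4a (0.21), and 1 passed when CF 3 was left out and 0 without WT 3 and CF 1. The mean level of the list was 12.71 ± 0.02 in CF and 12.66 ± 0.06 in WT.

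Transcripts of exocrine pancreas were present in all groups at very unequal levels. Of 11 pancreas and intestine markers, 0 rose and 0 fell in limma (adjusted over the list alone, 0 and 0; at unadjusted p under 0.05, 0), and their mean level was 9.12 ± 1.95 in CF and 8.80 ± 1.99 in WT (two-sided exact permutation p = 0.771). The list level was 11.6 in WT 3 and 11.6 in CF 1, against 6.96 to 8.79 in the other WT arrays and 7.18 to 9.74 in the other CF arrays. The digestive enzyme genes Cela2a and Amy2a5 differed by 0.19 and 0.45 between genotypes, and the median of the list was 0.45 while its camera test pointed lower. These are the 2 arrays left out in the counts given beside the gene groups.

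**Figure D2:**
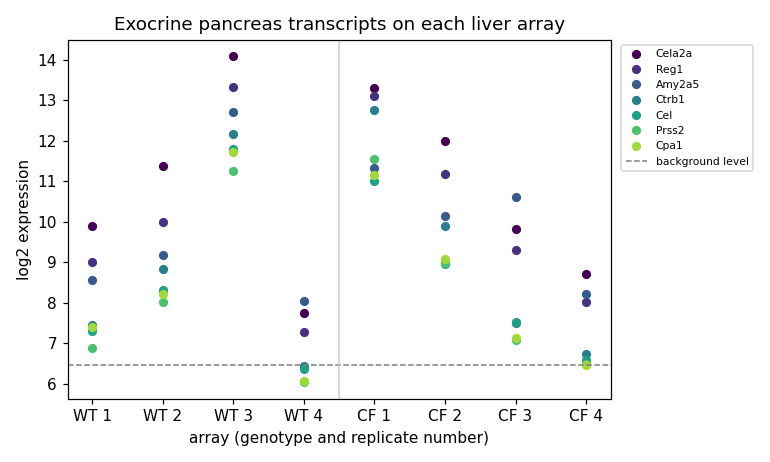
Log2 expression of 7 exocrine pancreas transcripts on each of the 8 liver arrays, WT left and CF right of the grey line; each colour is a gene and the dashed line is the background level of 6.47. WT 3 and CF 1 held the highest levels of their genotypes, with list means of 11.6 in both.

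Over all 33 lists, 11 were called by camera with a preset correlation, 4 higher and 7 lower in CF, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move on balance one way, 18 lists passed, and 31 passed its mixed test of change in either direction. The exact permutation of list levels gave its smallest p of 0.0286 for 17 lists, and their adjusted p was 0.0555. Cftr itself was read below background on all 8 arrays, at 6.06 ± 0.12 in CF and 6.11 ± 0.03 in WT, so its level could not be compared at this sensitivity (difference -0.05, two-sided exact permutation p = 0.657).

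**Figure D3:**
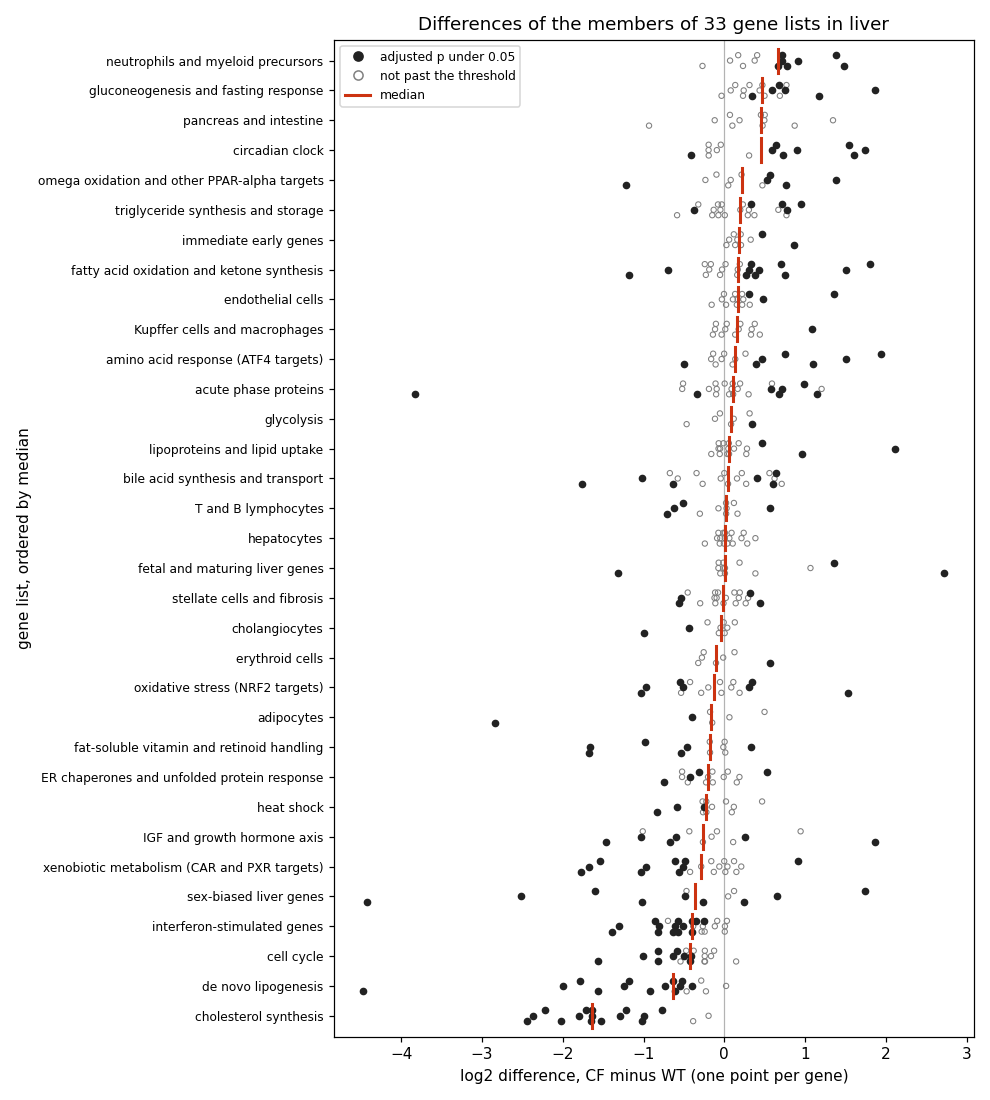
Log2 differences (CF minus WT) of the members of 33 gene lists, 1 point per gene; filled points passed adjusted p under 0.05, open points did not, and red bars are list medians. Cholesterol synthesis (median -1.64) and de novo lipogenesis (-0.63) lie farthest to the lower side and neutrophil markers (0.67) farthest to the higher side.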

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

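The tests of hepatocyte share, growth hormone signalling, time of day and tissue temperature were chosen only after the result each concerns had been seen. In 300 groups of 4 arrays examined, for named genes and list levels, 9 groups held a library far from the other 3, or 3%, where chance gives about 5%. Rbm3 was at 8.97 in WT 4, against 8.76 to 8.78 in the other WT arrays. Serpina3n was at 13.61 in CF 4, against 14.05 to 14.09 in the other CF arrays. Ifit3 was at 8.14 in CF 3, against 8.63 to 8.70. Ccnd1 was at 10.74 in WT 4, against 10.42 to 10.46. Ggcx was at 9.28 in WT 2, against 9.52 to 9.55. The heat shock list had a level of 9.51 in CF 3, against 9.44 to 9.45, and the oxidative stress list 9.69 in CF 4, against 9.38 to 9.43. The erythroid list had a level of 9.29 in WT 2, against 8.88 to 8.94. Cftr was at 5.89 in CF 1, against 6.10 to 6.13, all under background.

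Of the 35 splits of the 8 arrays, the real one gave 2474 changed probes and the highest of the others gave 3. A share of 1 in 35 is the smallest this test can give. The other splits mixed the genotypes within their groups, where the real contrast adds to the spread and can lower the count. Their low counts are therefore no measure of chance alone, and this test cannot by itself exclude chance for the count of changed probes. Chance cannot be excluded for the number of gene lists called by camera with the preset correlation, since 5 of the 35 splits, the real one included, gave at least 11 and the highest of the others gave 16. The other splits that reached 11 each exchanged 1 array between the genotypes and so kept part of the real contrast. Splits that exchanged 2 arrays gave at most 10, so this count decides little either way.

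Scd1, Mup6, Mup2, Hamp2, Hamp and Mup5 were the 6 named genes with the largest falls in CF. A smaller share of hepatocyte RNA would lower hepatocyte markers alike, and 5 such markers below log2 13, among them Alb on a weak probe, had a median difference of 0.2131, from -0.24 to 0.39. The Y-linked probes gave no sign of male animals among the WT libraries, with 0 arrays more than 1 log2 unit above background on 3 probes. Their highest reading was 6.76, for Uty. With no male array to show that these probes respond, they cannot exclude male animals. Whether growth hormone signalling was lower stays open, because Igf1, Igfals, Ghr, Socs2, Cish and Serpina12 had a mean difference of -0.8384 but were picked after their values were seen, while all 13 genes of the IGF and growth hormone list had a mean of -0.19, 2 higher and 4 lower (two-sided exact permutation p = 0.0857; camera adjusted p = 0.0582). The genotype itself stays open too.

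Per1, Per2, Per3, Ciart, Tef and Usp2 rose together in CF, with a median rise of 1.22. Livers taken at another time of day could give this, and Nr1d1, which peaks earlier in the day, differed by -0.4155 in the other direction, while Arntl differed by -0.04 (95% interval -0.36 to 0.27). The fall of Nr1d1 did not pass without WT 2, WT 3 or CF 3, with the replicate block, or without WT 3 and CF 1 together. A lower tissue temperature could also give these rises, as Rbm3 and Cirbp were higher (2.14 and 1.63) and the heat shock list had a median of -0.2223. A glucocorticoid response cannot be told apart from these, because 10 tested genes of a glucocorticoid-induced list had a median of 0.1417 (two-sided exact permutation p = 0.486), with 1 gene higher and 1 lower past the threshold. The hour of sampling is not in the labels, so the genotype and the hour stay open together.

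WT 3 and CF 1 deviated from their genotypes in the same way, with deviations that correlated at 0.586 across probes. Pancreatic RNA carried into these liver samples is a candidate explanation, as both libraries, 2 of 2, held the highest pancreas and intestine list level of their genotype, 2.77 and 2.44 above its mean, with Ctrb1 at 12.16 and 12.75 and Reg1 at 13.33 and 13.11. Sterol-regulated genes set differently in these animals cannot be told apart as a further source, since both libraries lay above their genotype mean for the cholesterol synthesis list, by 0.1028 for the smaller deviation, but CF 2 lay higher than CF 1.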

How the results depend on the processing

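Chosen after the data were seen were the filter on all 8 arrays, the stricter background level, cyclic loess, the floor at background, the covariate and leaving out WT 3 and CF 1. The other alternatives were planned. The 2474 changed probes (1337 higher, 1137 lower in CF) became 1440 (750 and 690) with the replicate number as a block; the cause was not tested. The count was 678 (324 and 354) with a fold of at least 1.5 also required, a smaller set by construction, and 1060 (531 and 529) with fewer arrays, without WT 3 and CF 1. Leaving out each library in turn gave 1612 to 2090 changed and 853 to 1158 higher, both lowest without WT 3. The number of lists called, 11, was 7 with probes above background on all 8 arrays, without xenobiotic metabolism, circadian clock, heat shock and endothelial cells, and 0 with an estimated correlation, where the lipogenesis shift stayed at -0.63 with adjusted p = 0.0892; the cause was not tested. The circadian clock, heat shock and retinoid handling lists also lost their calls with an estimated correlation. Their estimates were -0.030, -0.058 and -0.023, below the preset 0.01, so a correlation above the preset value did not end these calls. The stricter background level ended the heat shock call. In the settings run, 0 of the 2474 calls turned their sign past the threshold. The block kept 1398 of these probes, the covariate 2238, cyclic loess 2287, and leaving out WT 3 and CF 1 kept 1040. Under cyclic loess the share of changed probes that were higher was 47.5%, against 54.0%. Of 116 named genes, 30 lost their call without WT 3 and CF 1, 14 with the block and 8 with the trended, robust prior, among them Igf2 (adjusted p = 0.0677), Igfbp1 (0.0662), Hamp2 (0.0819), Hamp (0.0551) and Cyp51 (0.0557). Planned but not run, because scanner columns could not be given to samples, were no background correction, normexp with another offset, scaling to an upper quartile, detection p filters and the slide block; the deposited values, planned as an alternative, are the values reported. Signal over background limits genes near the level of 6.47, Cftr among them.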

Other observations

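The scan of gene families in this part was chosen after the values were seen. Genes were grouped by the stem of their symbol into 306 families of at least 5 tested genes, and changed genes were counted in each by a one-sided Fisher's exact test against all tested genes, adjusted over both directions. In all, 5 families were enriched. Histone H2B genes of the replication-dependent clusters were the clearest, with 7 of 8 lower in CF and 1 higher (adjusted p = 0.000179, median difference -1.01). Among them H2bc15 fell by 1.07 on the log2 scale, H2bc11 by 1.06 and H2bc4 by 0.72, while H2bc18 rose by 0.38. These genes share much sequence, so their probes are not independent. Under cyclic loess 7 were lower and 1 higher, and without WT 3 and CF 1 the numbers were 7 and 0.

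Of 52 tested cytochrome P450 genes, 17 were lower and 6 higher in CF (adjusted p = 0.000332 for the lower direction). Outside the lists described above, Cyp4f14, a fatty acid hydroxylase, fell by 1.68 and Cyp2f2, a naphthalene-oxidising enzyme, by 1.46. Without WT 3 and CF 1, 10 were lower and 2 higher. Of 7 lipid transporter genes of the Abca family, 5 were lower and 0 higher (adjusted p = 0.0143), with Abca8a at -1.77 and Abca3, a phospholipid transporter, at -0.88. The Mup family had 5 of 5 lower (Fisher's exact test, adjusted p = 0.00106). Its probes share much sequence too, so they are not independent and this p-value overstates the evidence. Mup6, Mup2, Mup5 and Mup20 had also been named among the largest falls already. Symbols beginning with Rps, most of them small ribosomal subunit proteins and a few of them kinases, had 10 of 27 higher and 0 lower (adjusted p = 0.0449), with Rps13 at 0.43 and Rps10 at 0.39. That count was 4 under cyclic loess and 1 without WT 3 and CF 1.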
